A study of Zea mays with 24 samples.

How the data were processed

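Anthers of the maize male sterility 8 mutant, called ms8 here, and of its fertile siblings were collected at lengths of 1.0, 1.5 and 2.0 mm, per the labels. The 6 groups held 4 biological replicates each, 24 samples in all. Per the labels' protocols, total RNA was amplified, labelled with Cy3 or Cy5 and hybridised to an Agilent maize array with 2 channels.

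The 24 scanner files formed 12 pairs of identical content, since each array carried 2 samples of one group. Replicates 1 and 2 shared one array and replicates 3 and 4 another, with the odd-numbered replicates in Cy3 and the even-numbered ones in Cy5. Each sample was therefore read from its own channel, and the comparisons between groups rest on 2 arrays per group. The arrays lay on 4 slides, each scanned on its own. Slide 1 held ms8 at 1.0 and 1.5 mm, slide 2 held ms8 at 2.0 mm, slide 3 held the fertile siblings at 1.0 and 1.5 mm, and slide 4 held them at 2.0 mm. Slide and genotype cannot be told apart, and a fit with the slide as a block was not run because every group lay on 1 slide.

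The spot intensity of each channel was taken by the authors with Agilent Feature Extraction 9.5.3.1, per the file headers, as the mean pixel signal with the median pixel signal of the local background. A processed intensity, background-subtracted, detrended and dye-normalized by the same program, was also in the files, together with flags of each spot, set to 0 or 1 by that program per the file headers. The deposited value table held linear intensities that share one distribution in all 24 columns, and each column ranked the spots like the median signal of its own channel, with a rank correlation of at least 0.997. Its median was 167 in every column. Whether a step within arrays preceded that quantile normalization is not stated.

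Intensities were corrected with the normexp method and an offset of 50, normalized within arrays by loess with control spots at weight 0, and between arrays by the Aquantile method of limma 3.58.1 in R 4.3.3. Log2 values of each channel were then used. Of 1008816 spot values of non-control probes, 1753 marked as outliers by the program were set aside. Most came from 2 fertile arrays, with 212 and 531 in replicates 3 and 4 at 1.0 mm and 297 and 348 in those at 2.0 mm. No ms8 sample had more than 30, so spot quality differed between the genotypes. Of 42034 non-control probes, 36503 were well above background in at least 3 of the 4 samples of at least 1 group, and 36500 of them could be tested in every comparison. Where a probe was well above background in no sample of a group, the size of its difference is not given. Between 28756 and 36689 probes were well above background per sample. The number of arrays limits the precision.

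Group means with a dye term were fitted to all 24 samples by the generalized least squares of limma, with the 2 samples of an array tied through a consensus correlation of 0.43, and the variances were moderated with 2.12 prior degrees of freedom. Own code made this fit. For probes without missing spots its estimated differences were checked against lmFit, from which they differed by at most 2.3e-14. Standard errors and p-values were not compared. P-values were adjusted by the Benjamini-Hochberg method over the probes tested, and a probe was called at an adjusted p under 0.05. All 6 groups share one estimate of the spread, because 2 arrays per group give few degrees of freedom. The fit took 17 residual degrees of freedom, counted over the 24 samples and not over the 12 arrays. Samples of 1 array thus still counted separately, tied by 1 correlation for all probes, so p-values may be too small. The comparisons were ms8 against fertile siblings at each length, the 2 steps between lengths in each genotype, and the 2 interactions of genotype and step. The change from 1.0 to 2.0 mm in each genotype was fitted as well, to define the stage index.

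The stage index placed each sample on the line from the mean of the fertile siblings at 1.0 mm (index 0) to their mean at 2.0 mm (index 1). The line ran over 1411 probes that were called between those groups and had a value in every sample. For each replicate number, the fertile samples of that number were left out of the means that define the line. Indices and numbers of detected probes were compared by exact two-sided permutation tests over 70 assignments, whose smallest p is 0.0286. These tests treat the 2 samples of an array as independent. In paired form, over 16 sign changes, such a test cannot pass 0.05.

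All 42034 probes carried the description Unknown. Only 23 probes, for 11 names, had a gene name in the files or in the table of reference genes, which matched the accessions of 4 probes. Of 28 gene lists fixed before the data were examined, 2 had members: meiosis (AM1, ZmSGO1, ZmSMC1 and ZmSMC3) and transposons (MUDR-TIRA, MUDRA, MUDRA-21 and MUDRB). The other 26 lists, among them anther fertility, pollen wall lipids, carbohydrate metabolism, cell cycle and mature pollen, could not be tested. Lists were tested with camera at a preset correlation of 0.01 between genes, and also with an estimated correlation and with fry, which tests whether the members move one way on balance. The plan was 1 probe per name, the one with the highest mean, but these tests take no missing values. They therefore ran on probes with a value in all 24 samples, which left MUDRA-21 out of the transposon list and put A_92_P016751 in place of the brighter A_92_P001166 for AM1. Counts and medians of a list use the brightest probes of all 4 names. After the results were seen, camera was also run on the moderated statistics of all probes, with those 2 brightest probes kept.

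Genes were to be named where they carried a symbol, passed the threshold and showed no overlap between the groups, up to 7 in each direction per genotype comparison, 5 per step and 4 per interaction. Where none passed, the 4 with the smallest p were to be given as not passing. A name with several probes was represented by the probe with the highest mean. Since so few probes had names, the probes with the highest and lowest called differences are also given by their identifiers, a choice made after the values were seen.

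Same-numbered samples of one genotype carry one plant code in the labels, so the numbers pair the samples across lengths. The deviations of such samples from their group means correlated across probes with r between -0.0986 and 0.723 over the pairs of neighbouring lengths, probes not being independent replicates. Across genotypes, same-numbered samples share the number and the dye but no plant. Their deviations at 1 length correlated with r between -0.347 and 0.408, a range that overlaps the one above.

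On simulated arrays with the measured means, variances and array correlation, 200 of 36503 probes were changed by known amounts. For ms8 against fertile siblings at 1.5 mm, 16.7%, 54.7%, 85.3% and 95.3% of the changed probes were recovered at log2 differences of 0.5, 1, 2 and 3, with a mean of 9 false calls among 135. When the array correlation was drawn anew for each probe, false calls rose to 47.7 of 175.7 on average. For the interaction of genotype and the step from 1.0 to 1.5 mm, 2.67%, 32.7%, 66.7% and 86.0% were recovered.

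Alternatives covered the processed signal minus its 75th percentile, quantile normalization of all channels, no background subtraction, the deposited value table, no filter on dim probes, no array block, no dye term, the replicate number or plant as a block, a fit of only the groups compared, a log2 fold change of at least 1 and leaving out each sample in turn. Others, added after the data were seen, were the plant as a block for the interactions, one mean per array, leaving out each of the 2 fertile arrays with most outlier spots, and leaving out probes in patches of uneven spots. A spot counted as uneven where the 2 arrays of a group differed by more than 2 on the log2 scale, and a patch was any spot with at least 4 uneven ones in the surrounding window of 49 spots. By this definition 1066 of the tested probes lay in a patch in at least 1 group. They numbered 178, 303 and 546 in the fertile siblings at 1.0, 1.5 and 2.0 mm, and 0, 74 and 0 in ms8. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.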

Results

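Transcript levels were measured in anthers of ms8 plants, which are male sterile, and of their fertile siblings. Each genotype was sampled at anther lengths of 1.0, 1.5 and 2.0 mm, with 4 samples per genotype and length. Between 68.4% and 87.3% of the 42034 probes were well above background in a sample. No probe carried a description, so 11 gene names on 23 probes could be followed, and other probes are given by identifier only. All differences are on the log2 scale, with adjusted p from the fit described above, which is called limma here. The samples of a genotype at 1.0 and 1.5 mm lay on 1 slide and those at 2.0 mm on another, so a change to 2.0 mm, like a difference between genotypes, cannot be told apart from slide and scan.

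The first comparison asked what the mutation changes at 1.0 mm. A_92_P006994 was lower in ms8 by -4.45 (SE 0.22, adjusted p = 9.3e-10) and A_92_P022455 by -2.84 (SE 0.32), each without overlap between 4 and 4 samples. A_92_P036856 was higher by 2.18 (SE 0.39, adjusted p = 0.0328) and A_92_P030789 by 1.87 (adjusted p = 0.0215), calls lost in 10 of 21 and 5 of 20 alternatives. For A_92_P030789 the fertile mean rests on 2 samples of 1 array, since the spots of the other array were set aside. None of the 11 named genes passed in limma, where 2 had an unadjusted p under 0.05. The 4 with the smallest p were MUDRA-21 (-0.47, adjusted p = 0.407), MUDRA (-0.30, adjusted p = 0.528), ZmSMC1 (-0.65, adjusted p = 0.757) and ZmSMC3 (0.26, adjusted p = 0.819). The fertile mean of MUDRA-21 at this length rests on 2 samples of 1 array, here and in the step and interaction from 1.0 mm. MUDRA is the transposase gene of the MuDR transposable element, and ZmSMC1 and ZmSMC3 are subunits of cohesin, which holds sister chromatids together. The meiosis list had 0 of 4 members called and 0 when adjusted over the list alone, with a camera adjusted p of 0.954 and signs that differed, the test and the median (0.13) being positive and the mean (-0.03) negative. The transposon list had 0 of 4 called and 0 when adjusted over the list alone, with a camera adjusted p of 0.946. In limma 36 probes passed, 17 higher and 19 lower in ms8, and all 36 showed no overlap between the groups. Of all probes 12.8% showed none, where chance would give 2.86% if the 8 samples were independent, which samples of 1 array are not. The count was 22 without ms8 replicate 2 or without ms8 replicate 3, 23 without fertile replicate 3, and 4 with 1 mean per array.

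At 1.5 mm the lowest level in ms8 relative to the fertile siblings was that of A_92_P002164, with a difference of -4.83 (adjusted p = 0.000283). A_92_P006994 was again lower, by -4.06 (SE 0.22, adjusted p = 4.9e-09), a call that was lost (adjusted p = 0.0615) when only the 2 groups compared were fitted. A_92_P036856 was higher by 2.00 (adjusted p = 0.0264) and A_92_P000177 by 1.79 (SE 0.26, adjusted p = 0.00402), a probe singled out after its values were seen because the highest one lay in a patch of uneven spots. These 2 calls were lost in 4 of 20 and 3 of 20 alternatives, where adjusted p reached 0.391. None of the named genes passed in limma, where 3 had an unadjusted p under 0.05. The 4 with the smallest p were ZmSMC1 (-0.98, adjusted p = 0.267), ZmRAD21 (-0.27, adjusted p = 0.294), MUDRA (0.30, adjusted p = 0.304) and MUDRB (0.47, adjusted p = 0.413). ZmRAD21 encodes the kleisin subunit of cohesin, and MUDRB is the other gene of MuDR. The ZmRAD21 signal was weak in every group, with means from 6.48 to 6.80 by its brightest probe. In ms8 at 1.5 mm that probe was well above background in 3 of 4 samples. Another ZmRAD21 probe, A_92_P009368, was at 6.36 in the fertile siblings at 1.5 mm, well above background in 1 of 4 samples. MUDRB was high in ms8 replicates 1 and 2 alone (8.52 and 8.40), which shared an array. Replicates 3 and 4 (7.42 and 7.40) lay within the fertile range of 7.36 to 7.65. ZmSMC1 was lowest in ms8 replicates 1 and 2 (9.18 and 9.12). It was 10.47 and 9.89 in replicates 3 and 4, against 10.38 to 10.97 in the fertile siblings. All 6 probes of ZmSMC1 and ZmSMC3, a set chosen after the values were seen, had a negative difference (median -0.82, smallest adjusted p = 0.111), while at 1.0 mm 4 were lower and 2 higher (median -0.07, smallest adjusted p = 0.757). The meiosis list had 3 of 4 members lower and the transposon list 4 of 4 higher, each with 0 called and 0 when adjusted over the list alone. The meiosis member not lower was AM1 by A_92_P001166, whose fertile replicate 3 was at 5.90 (others 8.96 to 9.92). By A_92_P016751, the probe in the list tests, AM1 was lower, with means of 8.34 in ms8 and 8.70 in the fertile siblings. Camera gave each list an adjusted p of 0.0501, which did not pass. With an estimated correlation the adjusted p was 0.116 for meiosis and 0.163 for transposons, with fry 0.0278 and 0.0680, and without the filter on dim probes 0.0471 for each.

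In limma 215 probes passed at 1.5 mm, 141 higher and 74 lower in ms8. Of these, 214 showed no overlap, as did 13.1% of all probes, against 2.86% by chance among independent samples. Only 1 probe passed when the spread came from the groups compared alone, and 3 passed with 1 mean per array, where the 2 samples of an array no longer counted separately. It was 78, 105 and 107 without fertile replicate 1, 2 or 3, 131 without ms8 replicate 1 and 502 without ms8 replicate 3. It was 78 with the processed signal.

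At 2.0 mm MUDRA-21, a MuDR sequence, fell in ms8 by 0.60 (SE 0.14, adjusted p = 0.0366), with 7.73 ± 0.15 (SD, n = 4) in ms8 and 8.33 ± 0.10 (SD, n = 4) in the fertile siblings and no overlap. That call was lost in 9 of 20 alternatives, where adjusted p ranged from 0.00466 to 0.200, among them without ms8 replicate 3 (0.0608), fertile replicate 2 (0.0846) or fertile replicate 3 (0.0859). MUDRA (-0.34, adjusted p = 0.222), ZmRAD21 (0.23, adjusted p = 0.389) and AM1 (1.44, adjusted p = 0.404) did not pass. AM1 is ameiotic1, needed for entry into meiosis. Its fertile mean here rests on 3 samples. By A_92_P016751, the AM1 probe of the list tests, the means were 7.40 in ms8 and 7.08 in the fertile siblings. The 6 probes of ZmSMC1 and ZmSMC3 again all had a negative difference (median -0.75, smallest adjusted p = 0.0978). By its brightest probe, ZmSMC1 was low in ms8 replicates 1 and 2 alone (8.92 and 8.88), which shared an array, while replicates 3 and 4 (10.44 and 9.87) lay within or above the fertile range of 9.62 to 10.07. The transposon list had 1 of 4 members called and 2 when adjusted over the list alone, with a camera adjusted p of 0.704. The meiosis list had 0 called and 0 when adjusted over the list alone, with a camera adjusted p of 0.951 and signs that differed, the test and the median (-0.07) being negative and the mean (0.26) positive.

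Among probes without a name, A_92_P002164 was lower in ms8 at 2.0 mm by -6.27 (adjusted p = 1.2e-05) and A_92_P006994 by -4.17 (adjusted p = 3.0e-09). A_92_P002164 had mean levels of 10.10 (n = 2), 11.59 (n = 4) and 13.11 (n = 3) in the fertile siblings at the 3 lengths and of 7.78, 6.76 and 6.81 in ms8. A_92_P002318 was higher in ms8 by 1.82 (SE 0.47, adjusted p = 0.0483), a probe chosen after the values were seen and lost in 14 of 21 alternatives. In limma 750 probes passed, 257 higher and 493 lower in ms8, and 745 showed no overlap, as did 17.3% of all probes, against 2.86% by chance among independent samples. The count was 460 without fertile replicate 2, 474 without fertile replicate 3 and 307 without the fertile array that carried replicates 3 and 4. Only 8 passed when only the groups compared were fitted, and 4 with 1 mean per array. Of the 257 higher probes, 46 lay in patches of uneven spots on the fertile arrays, where 1.50% of the tested probes lay, and none of the 493 lower ones did. With the processed signal a smaller share of the calls was higher, as given below. Before normalization the 75th percentile of the Cy5 signal at 2.0 mm was 474 and 522 in ms8 and 2264 and 1523 in the fertile siblings. For Cy3 it was 420 and 465 in ms8 and 597 and 626 in the fertile siblings. Whether this gap bears on the counts was not tested.

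**Figure D1:**
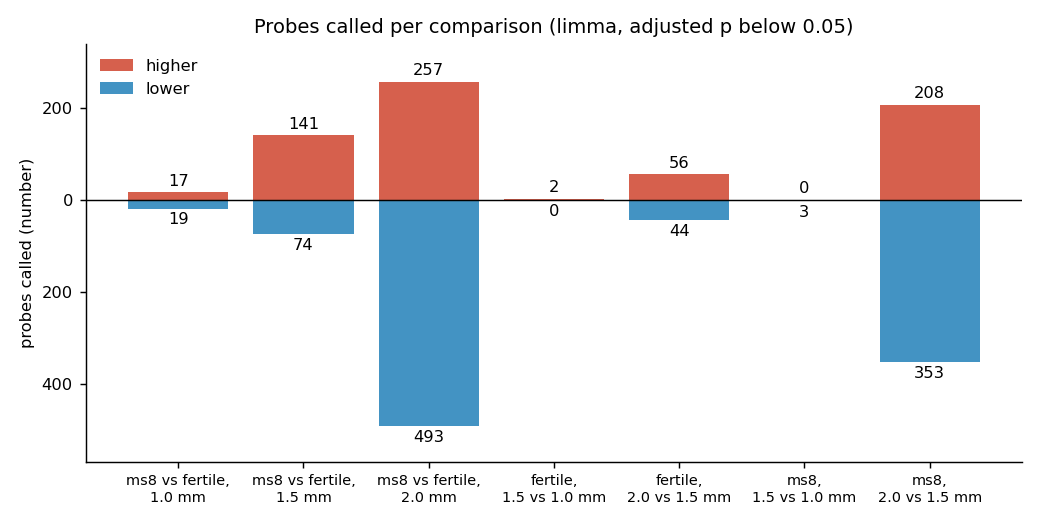
Numbers of probes with an adjusted p under 0.05 in each comparison, split into higher and lower. The count of ms8 against fertile siblings was 36 at 1.0 mm, 215 at 1.5 mm and 750 at 2.0 mm. Probes with an unadjusted p under 0.05 in limma numbered 3162, 5366 and 5535. No probe passed for an interaction of genotype and step, and with 1 mean per array the counts did not rise. A genotype difference that grows with length was therefore not shown.

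Across the lengths, 906 probes were called between the genotypes at 1 or more lengths, 821 of them at exactly 1 length. At all 3 lengths 10 probes were called, 5 higher and 5 lower each time, against 0.00436 expected if the calls were independent, which they were not, since the same plants were sampled at each length and the 1.0 and 1.5 mm samples shared slides. Between 1.5 and 2.0 mm, 74 probes were called at both lengths, 49 higher and 25 lower at each, and none in opposite directions. A_92_P006994, A_92_P022455, A_92_P013793, A_92_P023916 and A_92_P030420 were the 5 lower ones, with A_92_P030420 at -1.41, -1.55 and -1.64. A_92_P023916 was well above background in none of the 4 ms8 samples at 1.5 mm or at 2.0 mm. A_92_P034226 was higher by 1.48, 1.34 and 1.39.

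**Figure D2:**
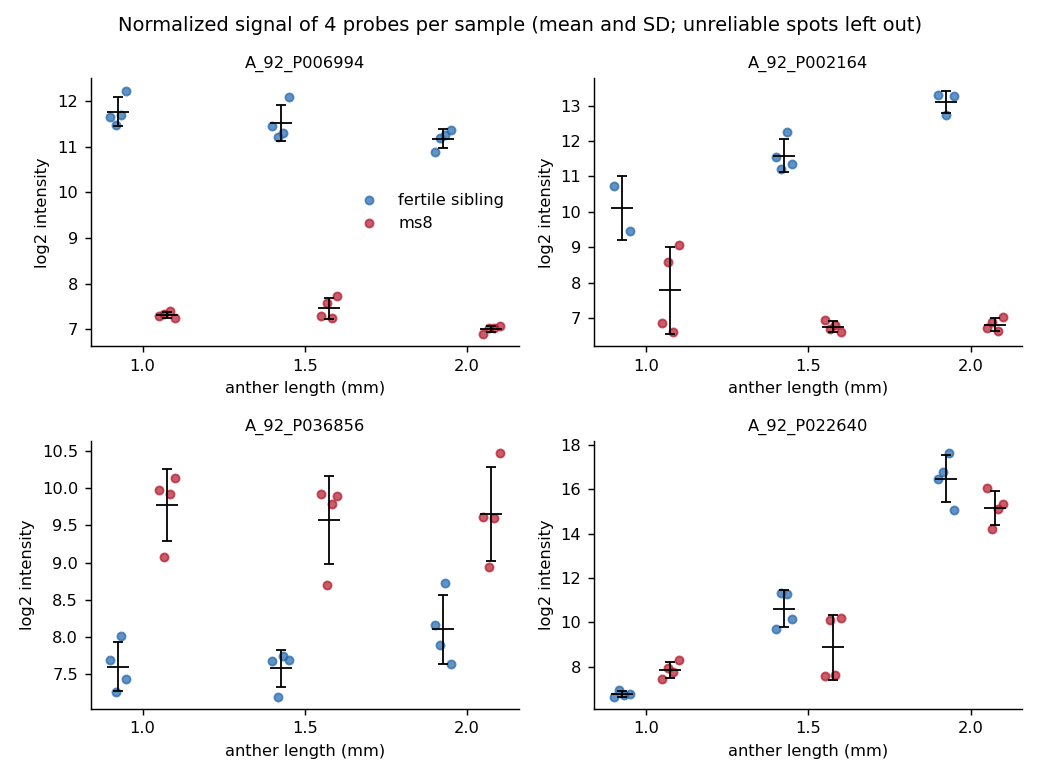
Log2 levels of single probes over the 3 anther lengths in ms8 and fertile samples, with points for samples, and the mean and SD, unreliable spots left out. A_92_P002164 reached 13.11 in the fertile siblings at 2.0 mm and 6.81 in ms8.

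The steps between lengths in the fertile siblings asked how the levels change as fertile anthers lengthen, the step to 2.0 mm being also a change of slide. From 1.5 to 2.0 mm, A_92_P022640 rose by 5.85 (SE 0.76, adjusted p = 0.0052) and A_92_P038586 by 5.29 (SE 0.91), while A_92_P009793 fell by 4.14 (SE 0.69) and A_92_P012220 fell by 2.89 (SE 0.57), calls lost in 1, 5, 4 and 8 of 21 alternatives. The meiosis list fell over this step (camera adjusted p = 0.00138, and adjusted p = 0.00697 with an estimated correlation), with 4 of 4 members lower, a median of -0.64, 0 called and 0 when adjusted over the list alone. The transposon list rose (camera adjusted p = 0.00285, and adjusted p = 0.0403 with an estimated correlation), with 4 of 4 members higher, a median of 0.55, 0 called and 4 when adjusted over the list alone. Those members are genes and sequences of 1 element family, and the test itself held 3 of them. No single named gene passed in limma, where 6 had an unadjusted p under 0.05. MUDRA-21 (0.49, adjusted p = 0.128), MUDRB (0.76, adjusted p = 0.169), MUDRA (0.33, adjusted p = 0.249) and MUDR-TIRA (0.60, adjusted p = 0.332) had the smallest p.

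In limma 100 probes passed over that step in the fertile siblings, 56 higher and 44 lower at 2.0 mm, and 1023 passed with the plant as a block, among them all 100. With the plant as a block the meiosis list had an adjusted p of 0.000146 and the transposon list 0.00218. The count was 11, 281, 168 and 14 without fertile replicate 1, 2, 3 or 4 at 1.5 mm, and 51, 9, 23 and 501 without replicate 1, 2, 3 or 4 at 2.0 mm. It was 415 without the fertile 2.0 mm array of replicates 3 and 4.

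From 1.0 to 1.5 mm in the fertile siblings, A_92_P017239 rose by 0.90 and A_92_P023599 by 0.63 (adjusted p = 0.0498 for each), calls lost in 14 of 21 alternatives. A_92_P017239 was well above background in 1 of 4 samples at 1.0 mm, so that the size of its change is uncertain. None of the named genes passed in limma, where 2 had an unadjusted p under 0.05. The 4 with the smallest p were ZMATP70 (0.83, adjusted p = 0.509), MUDRA-21 (-0.42, adjusted p = 0.520), LOC100279569 (-0.55, adjusted p = 0.710) and MUDRA (-0.20, adjusted p = 0.745). The meiosis list did not pass (camera adjusted p = 0.0828), and its adjusted p was 0.0376 with the plant as a block. With an estimated correlation it was 0.115, with the processed signal 0.293, and over the 6 alternatives it reached 0.535. The test and the median (0.15) of the list were positive and its mean (-0.00097) negative. For AM1 the mean used A_92_P001166, at 9.17 and 8.61 at the 2 lengths, and the test A_92_P016751, at 7.67 and 8.70. The meiosis list had 0 of 4 members called and 0 when adjusted over the list alone, as had the transposon list (camera adjusted p = 0.145). In limma 2 probes passed and 3142 had an unadjusted p under 0.05. With the plant as a block 1 passed, not among these 2. The count was 14 without fertile replicate 4 at 1.5 mm and 0 in limma without any other single sample, where the probes with an unadjusted p under 0.05 numbered from 2247 to 3518.

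In ms8 from 1.5 to 2.0 mm, A_92_P022640 rose by 6.29, A_92_P038586 rose by 5.67, A_92_P009793 fell by 4.56 and A_92_P012220 fell by 3.33, the same 4 probes that had the highest and lowest differences in the fertile siblings. This step too went from 1 slide to another. None of the named genes passed in limma, where 4 had an unadjusted p under 0.05. The 4 with the smallest p were MUDR-TIRA (0.75, adjusted p = 0.175), ZmRAD21 (0.32, adjusted p = 0.177), LOC100279569 (-0.87, adjusted p = 0.198) and MUDRA (-0.31, adjusted p = 0.246). The meiosis list had 4 of 4 members lower (median -0.25) without passing (camera adjusted p = 0.251), and the transposon list had a camera adjusted p of 0.905, where the test and the mean (0.04) were positive and the median (-0.15) negative. Each had 0 called and 0 when adjusted over the list alone. In limma 561 probes passed, 208 higher and 353 lower at 2.0 mm, and 1498 passed with the plant as a block, 555 of them shared. The calls were split nearly evenly between higher and lower with the processed signal, quantile normalization or the value table, as given below. The count was 1022, 978 and 97 without replicate 2, 3 or 4 at 1.5 mm, 855 and 70 without replicate 3 or 4 at 2.0 mm, and 0 when only the groups compared were fitted (unadjusted p under 0.05 in limma for 2960, and for 6297 in the fit of all groups).

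From 1.0 to 1.5 mm in ms8, A_92_P019995 fell by 1.16 and A_92_P026035 fell by 0.82 (adjusted p = 0.00432 and 0.0448), among 3 probes that passed in limma, where 1997 had an unadjusted p under 0.05. These calls were lost in 4 of 20 and 12 of 20 alternatives, and A_92_P026035 was well above background in 1 of 4 samples at 1.5 mm. None of the named genes passed, and MUDRA (0.40, adjusted p = 0.673), ZmRAD21 (-0.21, adjusted p = 0.987), MUDRA-21 (0.19, adjusted p = 1.00) and ZmSGO1 (-0.21, adjusted p = 1.00) had the smallest p in limma, 1 of the 11 under 0.05 unadjusted. ZmSGO1 encodes shugoshin, which protects cohesion at centromeres. The meiosis list had a camera adjusted p of 0.661 and 0 members when adjusted over the list alone, and the transposon list 0.168 and 1. With the plant as a block 1 probe passed, shared with the 3. The count was 6 without replicate 3 at 1.5 mm and 1 without replicate 1, 2, 3 or 4 at 1.0 mm or replicate 1 or 2 at 1.5 mm.

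**Figure D3:**
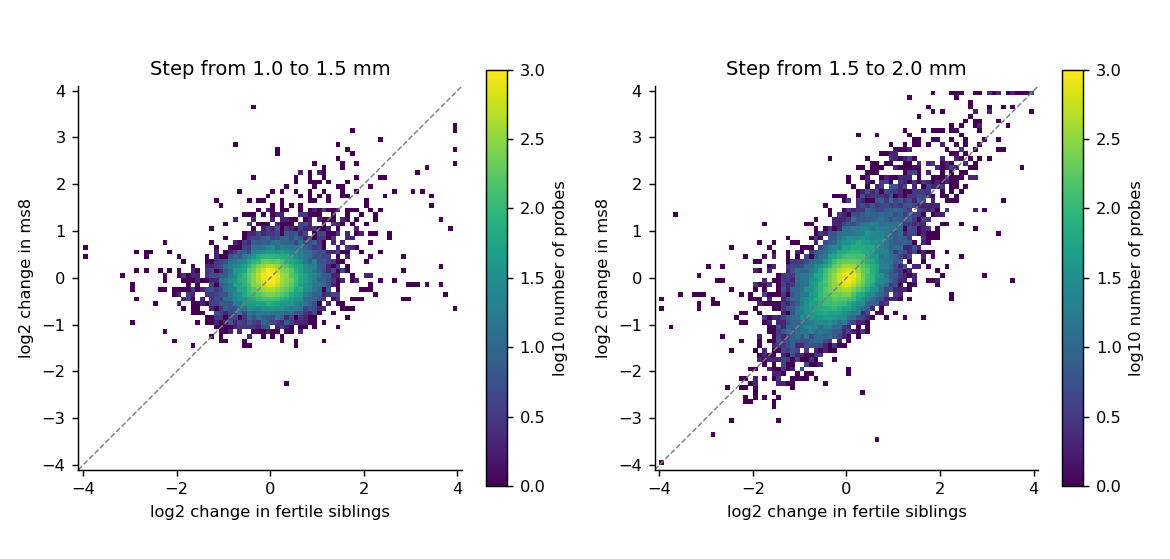
Log2 change of each probe over a step in ms8 plotted against its change in the fertile siblings, as the number of probes per bin, with changes clipped at -4 and 4. Across probes, which are not independent replicates, r was 0.17 for the step from 1.0 to 1.5 mm and 0.64 for that from 1.5 to 2.0 mm.

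Over the whole span from 1.0 to 2.0 mm, 722 probes rose in the fertile siblings, and 76.6% of them had a positive change in ms8, with a median of 1.09 in the fertile siblings and 0.58 in ms8. The 750 that fell had medians of -1.08 and -0.75, with 91.6% negative in ms8. These classes were chosen on the fertile samples, which favours larger changes there. Chosen on ms8, the 824 that rose had medians of 1.34 in ms8 and 0.87 in the fertile siblings, and the 1385 that fell had -1.04 and -0.62. Of the probes called over this span in both genotypes, 555 changed the same way, 232 up and 323 down, and 7 opposite ways.

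Whether the steps differed between the genotypes was tested as an interaction. No probe passed in limma for the step from 1.0 to 1.5 mm (unadjusted p under 0.05 for 2577) or from 1.5 to 2.0 mm (2699). With the plant as a block, a form added after the results were seen, none passed either (unadjusted p under 0.05 in limma for 3866 and 3797). The named genes with the smallest p were MUDRA (0.60, adjusted p = 0.587), MUDRA-21 (0.61, adjusted p = 0.622), ZmSMC3 (-0.44, adjusted p = 0.796) and ZMATP70 (-0.68, adjusted p = 0.836) for the first step. For the other they were MUDRA-21 (-0.74, adjusted p = 0.414), MUDRA (-0.64, adjusted p = 0.451), ZmRAD21 (0.50, adjusted p = 0.522) and MUDRB (-0.81, adjusted p = 0.652). From 1.5 to 2.0 mm the transposon list fell in ms8 relative to the fertile siblings (camera adjusted p = 0.0329), with 3 of 4 members lower, 0 called and 3 when adjusted over the list alone. That call was lost with an estimated correlation of 0.421 between members (camera adjusted p = 0.0972), and the adjusted p was 0.0953 with fry. The camera adjusted p was 0.0350 with the replicate number as a block, 0.0252 with the plant as a block and 0.00113 with all 4 members. For both steps these forms kept the preset correlation of 0.01, below the estimate, so a lower p there does not answer the loss. From 1.0 to 1.5 mm the list did not pass (camera adjusted p = 0.0559, 0 called, 2 when adjusted over the list alone), while its adjusted p was 0.0368 with the replicate number as a block, 0.0395 with the plant as a block, 0.120 with an estimated correlation and 0.00546 with all 4 members, a form of the test added after the results were seen. The meiosis list did not pass for either step (camera adjusted p = 0.0618 and 0.0789), with 0 called and 0 when adjusted over the list alone. Its camera adjusted p was 0.0368 and 0.0503 with the replicate number as a block, and 0.0395 and 0.0252 with the plant as a block. With an estimated correlation it was 0.120 and 0.0972, and over the 7 alternatives it reached 0.347 and 0.198. Without the fertile 1.0 mm array of replicates 3 and 4, 18 probes passed for the first step, and without the fertile 2.0 mm array of replicates 3 and 4, 6 passed for the other. The counts were 2 without fertile replicate 4 at 1.0 mm or at 1.5 mm for the first step, and 1 without fertile replicate 4 at 1.5 mm for the other.

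**Figure D4:**
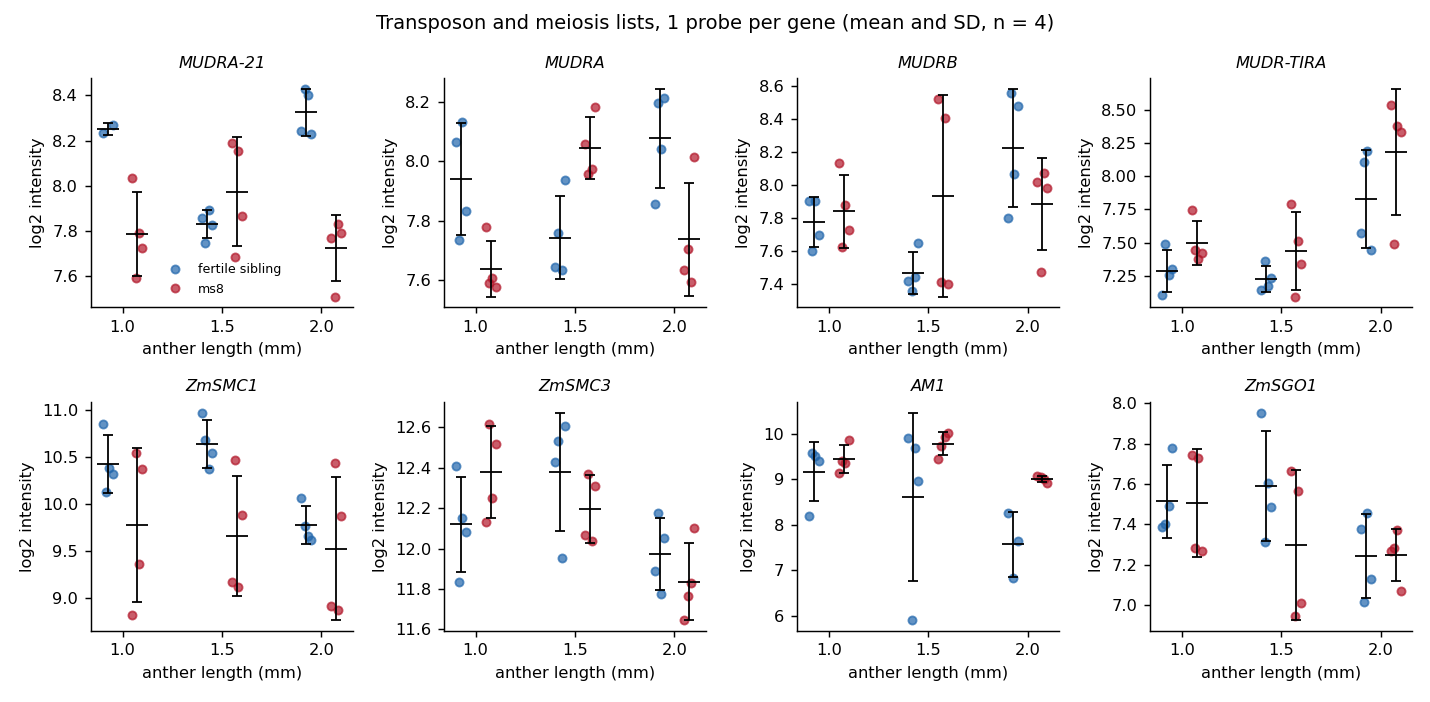
Log2 levels of the named genes in each sample, by genotype and anther length. MUDRA-21 at 2.0 mm, with means of 7.73 in ms8 and 8.33 in the fertile siblings, was the call among them.

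The stage index asked how far each sample lay along the fertile change from 1.0 mm (index 0) to 2.0 mm (index 1), over 1411 probes. At 1.0 mm it was 0.0661 ± 0.0637 in ms8 and 0.0106 ± 0.0620 in the fertile siblings (SD, n = 4, exact two-sided permutation p = 0.257). At 1.5 mm it was 0.211 ± 0.155 and 0.345 ± 0.243 (SD, n = 4, exact permutation p = 0.314). At 2.0 mm it was 0.870 ± 0.0650 and 0.979 ± 0.159 (SD, n = 4, exact permutation p = 0.229). Adjusted over the 3 lengths each p was 0.314, where the smallest p the test can give is 0.0286. Without fertile replicate 4 at 1.0 mm the difference there was 0.0960 (exact permutation p = 0.0286). The step from 1.0 to 1.5 mm spanned 0.145 in ms8 and 0.335 in the fertile siblings (n = 4, exact permutation p = 0.171). The 1411 probes were picked on all fertile samples, which draws fertile indices towards 0 at 1.0 mm and 1 at 2.0 mm. On an axis built from ms8 samples the order of the genotype means turned round at both lengths. There ms8 samples lay between -0.0685 and 0.151 at 1.0 mm, and fertile ones between 0.0452 and 0.183. At 2.0 mm the ranges were 0.903 to 1.06 and 0.744 to 0.938.

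**Figure D5:**
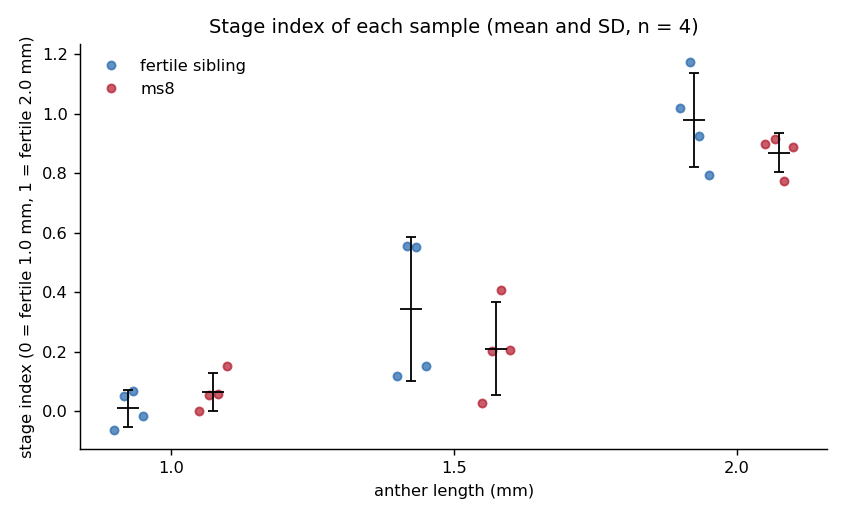
Stage index of each sample by genotype and anther length, with the mean and SD. Fertile samples at 1.5 mm lay between 0.120 and 0.557, and ms8 samples between 0.0292 and 0.409.

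The numbers of probes well above background did not pass a test between genotypes at any length. They were 34256 ± 1561 in ms8 and 32493 ± 2813 in the fertile siblings at 1.0 mm (SD, n = 4, exact two-sided permutation p = 0.343). The exact permutation p was 0.371 at 1.5 mm and 0.543 at 2.0 mm, with n = 4 per group. When probes were counted above the negative controls in place of the program's flag, the difference at 1.0 mm was 11612 (exact permutation p = 0.0286, n = 4). At 2.0 mm it turned from -747 to 10745 (exact permutation p = 0.0857, n = 4). By that count the means were 29848 in ms8 and 18236 in the fertile siblings at 1.0 mm, and 30633 and 19888 at 2.0 mm. The change of threshold thus lowered the fertile counts most, and why was not tested.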

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

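The tests of slides, developmental position, patches, plants, arrays and dyes below, and the count of splits that keep arrays whole, were chosen only after the results were seen, and the counts of other splits were planned before.

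The transposon list differed between the genotypes over the step from 1.5 to 2.0 mm (camera adjusted p = 0.0329), a call that ended with an estimated correlation (adjusted p = 0.0972). Over 265 groups of 4 samples of named genes and probes, 16 had 1 sample far from the other 3, where 13.25 would be so by chance. AM1 was 8.20 in fertile replicate 1 at 1.0 mm, against 9.40 to 9.58 in the others. MUDRA was 7.78 in ms8 replicate 1 at 1.0 mm, against 7.58 to 7.61. In ms8 replicate 3 at 2.0 mm, MUDRB was 7.48 (others 7.98 to 8.07), ZmRAD21 was 6.74 (6.81 to 6.82) and A_92_P008445 was 11.37 (11.74 to 11.81). In fertile replicate 3 at 1.5 mm, A_92_P036856 was 7.20 (7.67 to 7.74) and A_92_P030789 was 8.28 (9.02 to 9.13). In ms8 replicate 3 at 1.5 mm, A_92_P036856 was 8.69 (9.79 to 9.92) and A_92_P026981 was 9.10 (9.62 to 9.64). In ms8 at 1.0 mm, A_92_P022455 was 6.97 in replicate 1 (6.59 to 6.63) and A_92_P030704 was 7.27 in replicate 3 (7.64 to 7.68). In the fertile siblings at 1.5 mm, A_92_P017239 was 7.33 in replicate 2 (7.12 to 7.15) and A_92_P030420 was 8.41 in replicate 4 (7.95 to 8.01). At 2.0 mm, A_92_P038586 was 10.20 in fertile replicate 4 (13.25 to 13.81), and A_92_P009793 was 8.26 in fertile replicate 3 (7.11 to 7.30) and 8.12 in ms8 replicate 1 (7.42 to 7.52).

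Other splits of the same 8 samples into 4 and 4 were fitted for each count. The 2 samples of an array are tied, and only 3 of the 35 splits keep arrays whole, which is too few for a share under 0.05, so the 35 splits give no test of chance. At 1.0 mm 1 of 35 splits, the real one, called as many as 36 probes (highest other 5, and 5 with arrays whole), and at 2.0 mm 1 of 35 called as many as 750 (highest other 89, and 0 with arrays whole). At 1.5 mm 3 of 35 called as many as 215, and a split of replicates 1 and 4 of both genotypes from the rest called 1405, which points to a structure of the samples (highest other 7 with arrays whole). The fertile step from 1.0 to 1.5 mm had 4 of 35 splits as large as its 2 probes, the highest calling 2810 by parting plants 1 and 4 from plants 2 and 3, again a structure of the samples. The fertile step from 1.5 to 2.0 mm had 3 of 35 as large as its 100 (highest other 225, and 5 with arrays whole). The ms8 steps had 2 of 35 as large as 3 (highest other 7) and 2 of 35 as large as 561. The highest other for that last step called 2602 and parted replicates 1 and 2 from 3 and 4, which keeps arrays whole and follows the plants, and 1498 passed with the plant as a block. Among the 8 splits that part every plant pair, the real one was the largest for 3 of the steps, with 1, 0 and 0 as the highest other, and 2 were as large for the fertile step from 1.5 to 2.0 mm (161). For the interactions all 35 splits were as large as a count of 0 in limma, which any split is, so that this tests nothing (unadjusted p under 0.05 for 2577 and 2699 probes), the highest other calling 0 and 477.

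The difference between the genotypes at 1.5 mm was weighed against the slides and against anther development. Of its 215 probes, 92.6% had the same sign at 2.0 mm on other slides, against 62.0% of all probes, which argues against an effect of single slides as the whole cause. An effect common to the slides of 1 genotype cannot be told apart from genotype, which stays open, and for an additive slide effect the 4 ratios of held-out medians, 1.0 mm over 1.5 mm, were 0.369, 0.539, 0.695 and 0.781. The largest did not lie below 0.8 by more than their SD, a bound set after these values were seen, so an additive slide effect stays open. Of the 215 probes 69.3% opposed the fertile change from 1.0 to 2.0 mm, against 55.7% of all probes. This is below a bound of 90% for a lag in development, set after the results were seen. The bound cannot decide, since the sign of the fertile change is uncertain for probes that changed little between those lengths. A lag in development therefore stays open.

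Of the probes called higher in ms8 at 2.0 mm, 10 had fertile arrays that differed by more than 2. All 10, or 100%, lay in a patch of uneven spots, with a median of 15.5 uneven spots among 48 neighbours, which argues against a difference between plants, since neighbouring spots belong to unrelated probes. Poor local hybridisation on 1 fertile array is a candidate explanation, and A_92_P000276 (3.52) and A_92_P008445 (3.23) were among the probes in patches. Their differences went down to 0.85 and 0.81 over the alternatives, and the calls were lost in 11 of 20 and 12 of 20. No biological explanation was tested.

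Fertile samples at 1.5 mm were spread in stage index, replicates 1 and 4 at 0.120 and 0.151 and replicates 2 and 3 at 0.557 and 0.553. Samples of 1 array differed by 30.9 times as much as the array means, which argues against an effect of whole arrays. The dye means differed by only 0.0175. A dye effect of opposite sign on the 2 arrays would also part replicates 1 and 4 from 2 and 3. Neither comparison can see such an effect, which stays open. On an axis built from ms8 samples the SD of the fertile 1.5 mm samples was 2.67 times the larger SD of the other fertile groups. This would go with different developmental positions at 1 anther length, a hypothesis found and tested on the same data. At 1.0 mm plants 1 and 4 also lay below plants 2 and 3 on the fertile axis (-0.0641 and -0.0157 against 0.0523 and 0.0699). They did so on the ms8 axis too (0.0452 and 0.0518 against 0.183 and 0.172). At 2.0 mm the answer depended on the axis. On the ms8 axis plants 1 and 4 (0.938 and 0.775) lay above their array mates 2 and 3 (0.915 and 0.744). On the fertile axis they (1.02 and 0.796) lay below those mates (1.17 and 0.927). A difference between plants that lasts over part or all of the lengths stays open.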

How the results depend on the processing

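The interactions with the plant as a block, the fits with 1 mean per array, without a fertile array or without patches, and camera with all 4 transposon members, were chosen only after the results were seen; the cause of a change was not tested unless stated. Counts follow the order genotype at 1.0, 1.5 and 2.0 mm, fertile steps, ms8 steps, interactions. Without an array block they were 575, 2884, 3169, 429, 2987, 80, 4630, 72 and 78, where samples of 1 array count as independent. The processed signal gave 78 at 1.5 mm, 22 for the first fertile step, 196 for the later ms8 step and 6 and 2 for the interactions. With it 16.9% of the 2.0 mm calls were higher (34.3% before) and 78.8% of the later fertile step (56% before), and medians shifted by 0.14 for that step and by -0.16 for the later interaction. Of the calls of the later ms8 step 49.5% were higher with it, 48.9% with quantile normalization and 50.2% with the value table (37.1% before). The first fertile step gave 9 with quantile normalization, 6 without background subtraction, 0 with the value table, 9 without the filter and 10 without the dye term. Without background subtraction the later fertile step gave 60, the first ms8 step 7 and the later interaction 1. The first ms8 step gave 0 with the value table and the later interaction 1 without the filter. With replicate number or plant as a block the counts were 332 at 1.5 mm, then 1, 1023, 1 and 1498 for the steps. Fitting only the groups compared gave 52 at 1.0 mm, 17 of them shared, 1 and 8 at 1.5 and 2.0 mm and 1, 1, 0 and 0 for the steps, with fewer degrees of freedom. A log2 change of at least 1 left 20, 89, 211, 0, 57, 1 and 340. One mean per array gave 4, 3 and 4 between genotypes, 1 for the first fertile step, and 0 and 901 in ms8. Leaving out the fertile 1.0 mm array with replicates 3 and 4 gave 18 for the first fertile step and 18 for the first interaction, and the fertile 2.0 mm one 307, 415 and 6. Leaving out probes in patches gave 695 at 2.0 mm. For the counts of 0 in limma, unadjusted p was under 0.05 for 3286 probes (first fertile step) and 1998 (first ms8 step) with the value table. It was for 1112 and 2960 (ms8 steps) with only the groups compared, for 3142 with the log2 limit and for 1674 with array means. Leaving out 1 sample gave 22 to 36, 78 to 502 and 460 to 795 between genotypes, 0 to 14 and 9 to 501 in fertile siblings, 1 to 6 and 70 to 1022 in ms8, and 0 to 2 and 0 to 1 for interactions. The stage index difference at 1.0 mm ranged from 0.0218 to 0.0960, and detected probes at 1.0 mm differed by 11612 with negative controls. Lists past the threshold numbered 3, with 2 by an estimated correlation, 3 by fry, 3 with the processed signal, 5 without the filter, 6 with the block and 4 with all members. A_92_P001549 at 2.0 mm turned to -0.31 with the processed signal and -0.0180 with the value table. Single probes kept their call or lack of one in 632 cases, lost it in 141 and gained it in 15, named genes in 792, 9 and 7, and lists in 100, 2 and 10. A block for the slide was not run, since every group lay on 1 slide.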

Other observations

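The comparisons below were chosen only after the results were seen, and no explanation was tested for them. In ms8, plants 1 and 2 differed from plants 3 and 4 without overlap at 1592 of 35389 probes over 6 and 6 samples of the 3 lengths, 147 of them at least 2-fold. The other ways of parting the ms8 plants into pairs gave 54 and 64 probes, and the fertile plants gave 152, 205 and 47. ZmSMC1, a cohesin subunit, was 9.05 ± 0.21 (SD, n = 6) in ms8 plants 1 and 2 and 10.26 ± 0.30 (SD, n = 6) in ms8 plants 3 and 4 by its brightest probe, each n being 2 plants at 3 lengths, with ranges of 8.83 to 9.37 and 9.87 to 10.54. By the other ZmSMC1 probe, A_92_P006198, the ms8 pairs overlapped, at 8.04 ± 0.41 (7.58 to 8.69) and 8.67 ± 0.90 (7.37 to 9.38). In the fertile plants the brightest probe was at 10.39 ± 0.49 and 10.18 ± 0.42 (SD, n = 6). These pairs of ms8 plants also shared arrays.

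Some accessions were measured by more than 1 probe. Of the probes called at 2.0 mm, 74 had such a sibling, which had the same sign for 45 and was called for 4, and the sibling's difference had a median of 0.105 times that of the called probe. At 1.5 mm 22 of 30 siblings had the same sign and 2 were called. At 1.0 mm 2 of 3 had the same sign and none was called. Spike-in levels differed by -0.50, 0.79 and -0.05 between ms8 and fertile samples at the 3 lengths (exact permutation p = 0.171, 0.2 and 0.629, n = 4).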
